A study of Arabidopsis thaliana with 42 samples.

How the data were processed

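RNA from Arabidopsis thaliana seedlings grown for 10 days in the light was measured on 42 one-colour Affymetrix arrays, with 3 arrays for each of 14 groups. The labels place 27 arrays in a set of single mutants with Col controls of its own and 15 arrays in a set of higher order mutants with other Col controls. Per the labels' protocols, seeds received a cold treatment of 2 days at 4 C, seedlings grew at 25 C with 16 hours of light per day, and biotin-labelled cRNA was made from 10 ug of total RNA. The titles call the arrays of a group biological replicates, and p-values measure the spread between these samples.

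The values used are the authors' deposited log2 expression values, 1 per probe set and array, which per the submitters' processing notes were made with RMA, a method that corrects background, normalizes by quantiles and summarises the probes of a probe set. The version of RMA and the arrays it was run on together are not given in the sources used here. Array medians lay between 6.77 and 6.83 in the single set and between 6.24 and 6.31 in the higher order set, so the sets appear to have been normalized apart. Every test was therefore made within a set, and levels are never set against each other across sets. RMA compresses the differences of dim probe sets, and background-level signals still receive a value, so a low level does not show that a transcript was present. The number of arrays, 3 per group, limits the precision.

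Probe sets were named from the platform annotation given for this work and the RefSeq gene table of the TAIR10.1 assembly, which served only for names and gene order. Of 22810 probe sets, 64 controls were left out of the tests and 22746 were tested. A single gene was named for 13513 of these, 503 matched several genes and 8730 were unnamed here. Among the probe sets with a single gene, 11933 carried only a locus code and 1580 a gene symbol. A probe set with several genes was never used to name a gene. No ACC synthase gene had a named probe set, so the mutated genes could not be looked up in their own lines, and the planned comparison of their levels was not run.

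Linear models were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), with 1 coefficient per group and no filter. All groups of a set shared the estimate of the spread. Each single line and each higher order line was compared with the Col arrays of its own set. Direct comparisons were made between lines named for the same gene (acs2B with acs2C, acs5C with acs5D) and between hexa and penta, hepta and hexa, miR and hepta, and miR and hexa. An F-test asked in each set whether any group differed from Col. P-values were two-sided and adjusted by the Benjamini-Hochberg method within each comparison, and a probe set was called at an adjusted p below 0.05. Values are given as mean log2 level ± SD with n = 3 unless stated, and differences as log2 differences with their SE.

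Groups, comparisons, tests, gene lists, the rule for named genes and most of the alternative settings were fixed before the data were examined. Of 22 gene lists with 269 entries, 34 entries had a probe set, 9 lists had none and 6 lists had at least 3 members and could be tested. Lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, adjusted over the lists and Col comparisons of a set. A further 16 gene families read from the annotation's names were added to the tests after the annotation was seen and before any value was. The brightest probe set stood for a gene with several.

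The genes named for a line are those with the largest rise and fall past the threshold in which every array of the line lay beyond every Col array, 10 and 10 for a higher order line, 5 and 5 for a single line and 3 and 3 for a direct comparison, and members of the fixed lists past the threshold. Because most probe sets carry only a locus code, the same rule was also applied to genes with a symbol, taking 5 and 5 or 3 and 3; this addition was made after the annotation was seen. A selection of the genes that meet the rule is described. The genes with the largest differences between a line and the other lines were chosen after their values were seen.

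The tests were run on simulated data first. With 200 of 22746 probe sets changed, the acs1A comparison recovered 88% of changes of 0.5 and 100% of changes of 1 on the log2 scale with 10 false calls, and the penta comparison 76% and 99% with 12 false calls. Of 20 lists of 10 probe sets, the planted list was called in both simulated comparisons, and of the remaining lists 0 were called with it in the acs1A comparison and 1 in the penta comparison.

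The 45 probe sets for bacterial and phage transcripts, which are added to a sample at labelling or at hybridization and do not come from the plant, were fitted in the same way as a check of the arrays. Because they split the single set, each single line was also compared with the mean of the other lines at the same level of the bioC hybridization controls, leaving out Col, for single probe sets, for members of the lists and for the lists as a whole. Lines were weighted equally in that mean. For acs5D, acs6E and acs9B it held 3 lines, of which acs2B was represented by replicate 2 alone. This comparison, a fit of acs2B and acs2C with that level as a batch term, a fit without acs4A replicate 1 and a fit without the miR arrays were chosen after seeing the data. Settings chosen beforehand were a filter on low values, a fit of the 6 arrays compared alone, the replicate number as a block, an intensity trend with a robust prior, a second quantile normalization and leaving out each array in turn. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.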

Results

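The series measured transcript levels in seedlings of Arabidopsis thaliana lines with mutations in the genes of ACC synthase (ACS), the enzyme family that makes the direct precursor of the plant hormone ethylene. Its title asks how the ACS isoforms act in combination. The single set held 8 lines named for 1 ACS gene each (acs1A, acs2B, acs2C, acs4A, acs5C, acs5D, acs6E and acs9B) and the wild type Col. The higher order set held 3 lines named penta, hexa and hepta, a line named miR, and Col. Each group had 3 arrays. The lists of ethylene-related genes were measured through few probe sets: EIN3 and RTE1 stood for perception and signalling, and the ACC oxidase gene AT1G12010 for the last step of synthesis.

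Transcripts added at labelling or hybridization separated the single-set Col arrays from every line. The bacterial labelling control thr lay at 6.51 to 6.68 on the 3 Col arrays and at 7.08 to 8.14 on the line arrays, and the phage hybridization control cre at 13.11 to 13.29 on Col against 12.55 to 12.91 on the lines. Of 45 such probe sets, 40 differed between acs1A and Col, 29 in acs2B, 41 in acs2C, 39 in acs4A, 37 in acs5C, 38 in acs5D, 35 in acs6E and 35 in acs9B. The bacterial hybridization control bioC split the line arrays further, with 14 arrays at 7.07 to 7.50 (acs1A, acs2C, acs4A, acs5C and acs2B replicates 1 and 3) and 10 arrays at 8.95 to 9.30 (acs5D, acs6E, acs9B and acs2B replicate 2). In the higher order set limma called 0 of the 45 probe sets against Col in penta, hexa and hepta (1, 0 and 0 at an unadjusted p under 0.05) and 3 in miR (15 at an unadjusted p under 0.05). Because these control transcripts parted the Col arrays from every line array, a difference in labelling or hybridization and a difference in genotype cannot be told apart in any comparison of a single line with Col, and differences from the other lines of the same bioC level are given for the genes and lists of most weight.

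**Figure D1:**
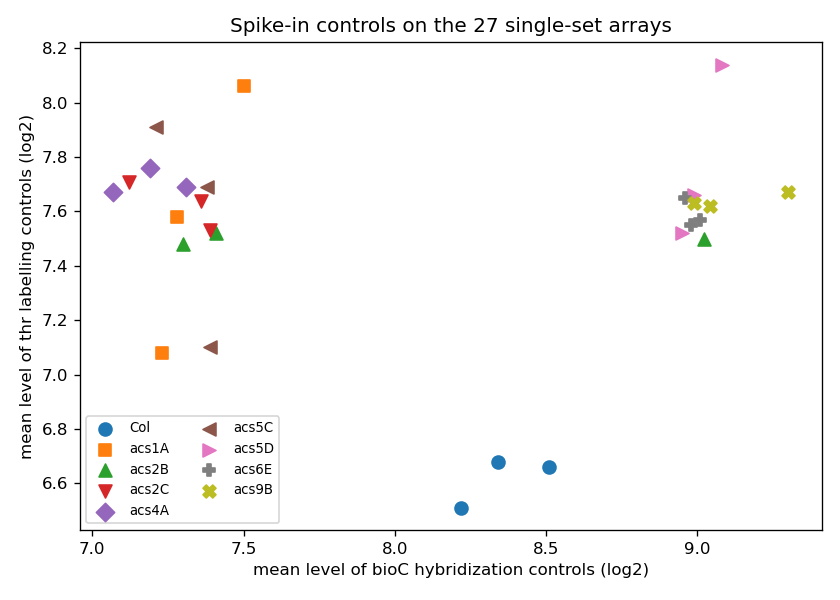
Mean level (log2) of the bioC hybridization controls on the horizontal axis and of the thr labelling controls on the vertical axis, 1 point per array of the single set. The 3 Col arrays lie at thr levels of 6.51 to 6.68, below all line arrays, and the line arrays fall at bioC levels of 7.07 to 7.50 or 8.95 to 9.30.

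Across the single lines, a shared group of genes separated the mutants from Col. AT5G10770 was higher in all 8 lines by 1.61 to 2.01, AT1G01320 by 1.1 to 2.39, AT5G24710 by 1.21 to 1.60 and the plastid gene psbB, which encodes a photosystem II core antenna protein, by 1.15 to 1.53. The cold-regulated gene COR15A was lower, with log2 differences of -0.84 in acs9B to -2.64 in acs6E, and so was the plastid gene psbN, with -1.27 to -1.60. The COR15A call in acs9B was lost without acs9B replicate 3 (adjusted p = 0.067). In total 523 probe sets were higher and 507 lower than Col in all 8 lines. Of 4 measured reference genes, 1 was higher in each line and 1 lower (2 in acs2C), with 2 or 3 adjusted over the list alone and camera adjusted p of 0.90 to 0.97. AT2G28390 (SAND family) lay 0.17 to 0.32 above Col, calls that were lost without Col replicate 1 in acs1A, acs2B, acs5D, acs6E and acs9B (adjusted p = 0.16, 0.061, 0.055, 0.057 and 0.081). The call was also lost in acs1A without any 1 of its own arrays or Col replicate 3, in acs2B without its replicate 2 and in acs9B without its replicate 2 or 3 (0.067 to 0.12). AT4G34270 (TIP41-like) was lower by -0.18 to -0.32 in every single line except acs9B (-0.10, adjusted p = 0.25). Its call was lost in acs4A without any 1 of the 6 arrays (0.051 to 0.11) and in acs5C without acs5C replicate 2 (0.058). GAPC2 was called lower in acs9B (-0.17, adjusted p = 0.026) and acs2C (-0.15, adjusted p = 0.046). The GAPC2 calls were lost in acs9B without acs9B replicate 1 or Col replicate 2 or 3 (0.053 to 0.11), and in acs2C without any 1 of its arrays or Col replicate 2 or 3 (0.083 to 0.17) and after a second quantile normalization (0.084). On the 6 arrays alone AT2G28390 passed only in acs2C and acs5C, AT4G34270 only in acs2B and acs6E, and GAPC2 in neither line. Against the other lines, AT5G10770 in acs1A differed by 0.10 ± 0.11 (SE), AT5G24710 by 0.18 ± 0.07, COR15A by -0.11 ± 0.17 and psbN by -0.09 ± 0.08, with limma adjusted p of 0.70, 0.16, 0.78 and 0.60. Some genes of the shared group did differ there: AT1G01320 was higher in acs6E by 0.84 ± 0.12 (adjusted p = 9e-05), and COR15A was lower in acs6E (-1.25 ± 0.19) and higher in acs9B (1.15 ± 0.19, adjusted p = 0.00017). AT2G28390 differed from the other lines by -0.10 to 0.08 and was not called in any, and AT4G34270 was called in acs9B (0.21, adjusted p = 0.0043). The Col arrays had the widest spread of the single set (median SD 0.120 against 0.0722 to 0.101 in the lines). The shared estimate of the spread averages over groups, so it may understate the error of comparisons with Col. Called probe sets numbered 4012 in acs5D to 6559 in acs6E against Col, with more lower than higher in each line. That balance depended on the scaling. After a second quantile normalization more were higher than lower in acs2B (2722 and 2488), acs2C (3130 and 2947), acs4A (2482 and 2105), acs5C (2090 and 2020), acs5D (2006 and 1973) and acs6E (3359 and 3106). In acs1A (2391 and 2414) and acs9B (2937 and 2943) slightly more stayed lower. They numbered 329 in acs5D to 6289 in acs9B against the other lines, where a large change in 1 line also lowers or raises the value of the rest.

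**Figure D2:**
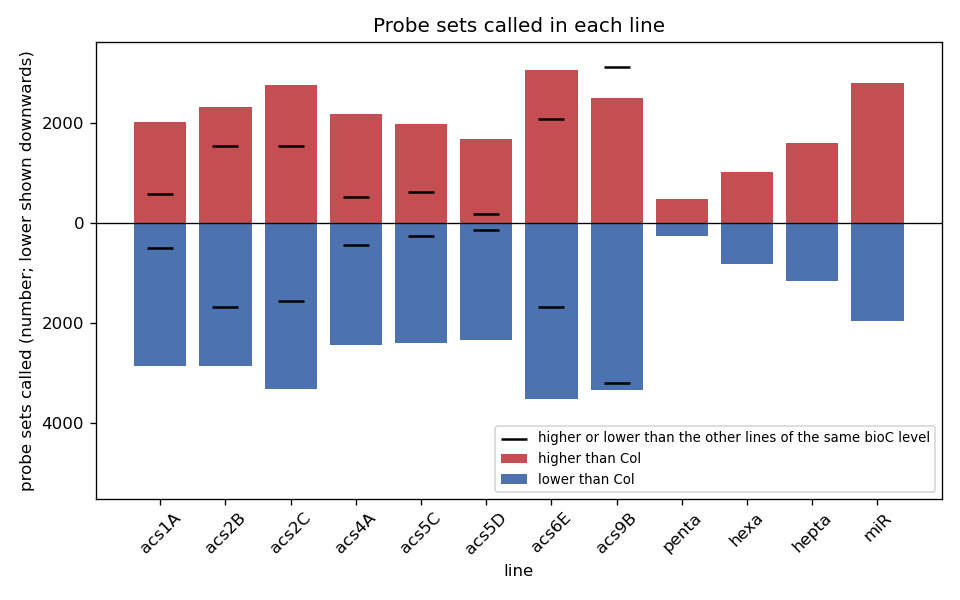
Number of probe sets called in each line against Col (bars, higher upwards and lower downwards) and, for the 8 single lines, against the other lines of the same bioC level (black marks). The bars run from 4012 calls in acs5D to 6559 in acs6E and from 729 in penta to 4748 in miR, and the marks from 329 in acs5D to 6289 in acs9B.

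In acs1A, AT3G07070 was the most changed gene. Its level was 9.16 ± 0.23 against 5.27 ± 0.21 in Col, a log2 difference of 3.90 ± 0.11 (SE, limma adjusted p = 4e-18). It was higher by the same 3.90 ± 0.08, 15-fold, than in the other lines (adjusted p = 1.5e-18). BHLH101, a transcription factor of the iron deficiency response, was at 4.50 ± 0.11 against 6.52 ± 0.71 in Col (-2.02 ± 0.30, adjusted p = 4.5e-05) and differed from the other lines by -1.23 ± 0.21 (adjusted p = 0.0016). The expansin-like gene EXLA2 was higher than in Col by 1.25 ± 0.20 and than in the other lines by 0.93 ± 0.14. EXO, a gene of brassinosteroid-promoted growth, was higher than in Col by 0.77 (adjusted p = 0.032) and than in the other lines by 1.5 ± 0.18 (adjusted p = 4.5e-05). Calls against Col numbered 2008 higher and 2852 lower, of which 499 (10.3%) were called in the same direction against the other lines, while 40 of 45 control transcripts also differed from Col. Both comparisons of a line use that line's own arrays, so recurrence in this and the other lines is not an independent check. Fitted on the 6 arrays alone, the comparison with Col gave 2319 calls.

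The lines acs2B and acs2C, named for the same gene, differed from each other at 4859 probe sets, 2371 higher and 2488 lower in acs2B. AT2G27420 was at 9.59 ± 0.08 in acs2B and 5.07 ± 0.10 in acs2C (4.53 ± 0.63, adjusted p = 3.4e-05). TBL26, a member of a family that acetylates cell wall polymers, was higher in acs2B by 2.68 ± 0.35 and HYH, a light-signalling transcription factor related to HY5, by 2.09 ± 0.28. AT3G62550 (-2.02 ± 0.25), the expansin-like EXLA1 (-1.90 ± 0.37) and PORB, an enzyme of chlorophyll synthesis (-1.48 ± 0.13, adjusted p = 1.6e-07), were lower in acs2B. By limma 0 of the 45 control transcripts were called between these lines, with 4 at an unadjusted p under 0.05. The bioC level was 9.02 in acs2B replicate 2, against 7.30 and 7.41 in its other arrays and 7.12 to 7.39 in acs2C. Such a spread within acs2B makes a call of hybridization controls unlikely, so the 0 does not show equal hybridization. With the bioC level as a batch term and Col left out, 4644 probe sets differed.

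Against Col, acs2B had 2314 probe sets higher and 2847 lower (2722 and 2488 after a second quantile normalization), and 29 of 45 control transcripts differed. AT3G62550 was at 7.62 ± 0.51 against 10.09 ± 0.63 (-2.47 ± 0.25, adjusted p = 3.3e-07) and PORB at 9.79 ± 0.17 against 11.28 ± 0.22 (-1.49 ± 0.13). TBL26 was higher by 1.34 ± 0.35 (adjusted p = 0.0076), a call that was lost without Col replicate 1 (adjusted p = 0.066). Against the other lines, the 2 acs2B arrays at the low bioC level differed by -1.91 ± 0.17 for AT3G62550, -1.18 ± 0.11 for PORB and 1.95 ± 0.31 for TBL26, all past the threshold. In acs2C, 2745 probe sets were higher and 3308 lower than Col, with 41 of 45 control transcripts different. AT2G27420 (-2.98 ± 0.63), AT1G60590 (-1.82 ± 0.37) and HYH (-1.41 ± 0.28) were lower, and AT4G16870 was higher by 1.75 ± 0.15. From the other lines these 4 genes differed by -2.89 ± 0.52, -1.71 ± 0.29, -1.30 ± 0.22 and 1.08 ± 0.10. The calls against Col that recurred in the same direction against the other lines were 1381 (26.8%) in acs2B and 1713 (28.3%) in acs2C. On the 6 arrays alone, 2543 and 3600 probe sets were called against Col.

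In acs4A, 2177 probe sets were higher and 2433 lower than Col, and 39 of 45 control transcripts differed. AT4G16870 was at 7.59 ± 0.07 against 5.98 ± 0.38 (1.62 ± 0.15, adjusted p = 8.5e-08) and EXO at 9.21 ± 0.49 against 10.50 ± 0.58 (-1.28 ± 0.25, adjusted p = 0.00084). AT4G16870 was higher than in the other lines by 0.92 ± 0.10 and EXO lower by -1.07 ± 0.18 (adjusted p = 0.0010). The circadian clock gene GI was higher than in Col by 0.61 ± 0.10 (adjusted p = 8.1e-05) and than in the other lines by 0.54 ± 0.08 (adjusted p = 0.00019). In acs1A GI was lower than in the other lines by -0.44 ± 0.08 (limma adjusted p = 0.0012) and differed from Col by -0.17. For acs4A 951 probe sets were called against the other lines, and 460 (9.98%) of the calls against Col recurred there. Replicate 1 stood apart from replicates 2 and 3 of this line, with a first principal component score of -26.8 against 5.9 and 13.8, and 571 probe sets were called on the 6 arrays alone, where EXO and GI did not pass (adjusted p = 0.077 and 0.063).

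The lines acs5C and acs5D differed from each other at 521 probe sets, 361 higher and 160 lower in acs5C. QQS, a regulator of starch content, was at 6.08 ± 0.10 in acs5C and 8.37 ± 0.06 in acs5D (-2.29 ± 0.11, adjusted p = 1.8e-12). SAG29, a SWEET-type sugar transporter of senescent leaves, was higher in acs5C by 1.52 ± 0.20 (adjusted p = 8.4e-05), and DFR, an enzyme of anthocyanin synthesis, by 0.76, a call that was lost without acs5C replicate 2 (adjusted p = 0.051). All acs5C arrays lay at the low and all acs5D arrays at the high bioC level, and 10 of 45 control transcripts differed, so bioC level and line cannot be told apart here. Leaving out 1 array changed the count to 239 without acs5C replicate 2, 340 without acs5C replicate 3, and 346, 299 and 251 without acs5D replicates 1, 2 and 3, and the 6 arrays alone gave 1068.

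Against Col, QQS was higher in acs5D by 2.28 ± 0.11 (adjusted p = 1.9e-12) and against the other lines by 2.18 ± 0.08, 4.53-fold (adjusted p = 7.2e-13). SAG29 was lower in acs5D by -1.27 ± 0.20 against Col and -1.0 ± 0.18 against the other lines, and AT4G16870 was higher by 1.58 ± 0.15 and 1.25 ± 0.11. In acs5C, AT1G26250 was higher than in Col by 1.33 ± 0.15 and PORB lower by -0.78 ± 0.13, but against the other lines they differed by 0.26 ± 0.10 and -0.17 ± 0.09 (adjusted p = 0.17 and 0.38). The iron-response gene BHLH101 was higher in acs5C than in the other lines, at 6.82 against 5.15 (1.67 ± 0.21, adjusted p = 6.7e-05). Col lay at 6.52 ± 0.71, and the difference of 0.30 from Col was not called (adjusted p = 0.53). The ACC oxidase gene AT1G12010, whose product makes ethylene from ACC, was lower in acs5C than in Col by -0.43 ± 0.10 (adjusted p = 0.0053) and than in the other lines by -0.40 ± 0.07 (adjusted p = 0.00083), but the 6 arrays alone did not call it (adjusted p = 0.094). This gene was higher than in the other lines in acs6E by 0.36 ± 0.07 (adjusted p = 0.0015) and in acs1A by 0.25 ± 0.07 (adjusted p = 0.032). The differences of these lines from Col, 0.23 and 0.09, were not called. Calls against Col were 1969 higher and 2388 lower in acs5C and 1672 and 2340 in acs5D, where 37 and 38 of 45 control transcripts also differed. Compared with the other lines 859 and 329 probe sets were called, with 328 (7.53%) and 140 (3.49%) of the calls against Col recurring there, and on the 6 arrays alone 1827 and 1836 against Col.

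With all arrays in the fit, acs6E had the most calls against Col of the single lines, 3043 higher and 3516 lower, with 35 of 45 control transcripts different. Leaving out 1 array gave up to 6344 calls in acs2C and up to 6208 in acs6E. AT3G62550 was at 6.81 ± 0.20 against 10.09 ± 0.63 (-3.27 ± 0.25, adjusted p = 3e-09), AT3G62950 was lower by -2.43 ± 0.37, AT3G15630 by -2.18 ± 0.35, CCL, a transcript of short half-life, by -2.0 ± 0.19 and PORB by -2.08 ± 0.13. AT4G19430 was higher by 2.07 ± 0.21 (adjusted p = 1.1e-07), and HYH by 1.11 ± 0.28. AT3G62550 differed from the other lines by -2.15 ± 0.16, AT3G62950 by -2.40 ± 0.31, AT3G15630 by -2.24 ± 0.30, CCL by -1.46 ± 0.15, PORB by -1.49 ± 0.10, AT4G19430 by 2.07 ± 0.18 and HYH by 1.34 ± 0.24. COR15A was lower than in Col by -2.64 ± 0.22 and than in the other lines by -1.25 ± 0.19 (adjusted p = 0.00015). Of the calls against Col, 2367 (36.1%) recurred in the same direction against the other lines. On the 6 arrays alone 4252 probe sets were called.

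In acs9B, 2483 probe sets were higher and 3337 lower than Col, with 35 of 45 control transcripts different. The expansin-like gene EXLA1 was at 10.21 ± 0.28 against 8.60 ± 0.75 (1.61 ± 0.37, adjusted p = 0.0026), XTH33, a xyloglucan-modifying enzyme, was higher by 1.31 ± 0.21 and the expansin EXPA16 by 1.18 ± 0.28. Relative to the other lines these genes were higher by 2.2 ± 0.31, 1.27 ± 0.16 and 1.51 ± 0.26. AT2G27420 was lower than in Col by -2.99 ± 0.63 and than in the other lines by -3.87 ± 0.57 (adjusted p = 5.8e-05), and HYH by -1.23 ± 0.28 and -1.80 ± 0.24. The mitochondrial gene cox1 was higher by 1.69 ± 0.11 and 0.91 ± 0.10. Relative to the other lines 3101 probe sets were higher and 3188 lower, and 2614 (44.9%) of the calls against Col recurred there. The other lines here were acs5D, acs6E and, through replicate 2 alone, acs2B. In their differences from Col acs6E and acs2B correlated at 0.86 with each other but at 0.28 and 0.30 with acs9B. Differences of acs9B from this mean thus depend strongly on those 2 lines. On the 6 arrays alone 2843 were called against Col.

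Of the lists named in advance, the cold and drought response list was called against Col in acs5D alone of the single lines. There 3 of 4 measured members were lower over all probe sets and 3 adjusted over the list alone, with a median of -0.74 (camera adjusted p = 0.0066, and adjusted p = 0.23 with an estimated correlation). COR15A was lower by -1.93 there and COR15B by -0.62, while COR47 differed by -0.12 and was not called. The COR15B call there was lost without Col replicate 2 (adjusted p = 0.077) and on the 6 arrays alone (0.16). In the other lines 2 or 3 of the 4 members were lower, and 2 to 4 adjusted over the list alone, with camera adjusted p of 0.065 to 0.26. Leaving out 1 array brought the list past the threshold in acs1A, acs2C and acs6E without Col replicate 2 (adjusted p = 0.046), in those lines and acs5C without acs2C replicate 2, acs9B replicate 1 or acs9B replicate 3 (0.031 to 0.048), and in acs1A without acs1A replicate 2 (0.036). The median against the other lines was -0.19 in acs5D and between -0.10 and 0.25 in the remaining lines, with adjusted p of 0.23 to 0.90. In acs5D COR15A differed from the other lines by -0.30 (adjusted p = 0.54) and COR15B by 0.00, and the probe set for KIN1 and KIN2 was lower by -0.51 (adjusted p = 0.022). In acs9B COR15A, COR15B and COR47 were higher than in the other lines by 1.15, 0.30 and 0.21 and the KIN1 and KIN2 probe set was lower by -0.30, in acs6E COR15A was lower by -1.25, in acs4A COR47 was higher by 0.20 and in acs2B the KIN1 and KIN2 probe set by 0.62, and no other member was called there.

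The auxin response list had 5 measured members. In acs2B 3 were lower (GH3.3 -0.44, WES1 -0.53 and IAA29 -0.62), in acs6E 2 (WES1 -0.67 and IAA29 -0.87), in acs9B 2 were higher (GH3.3 0.41 and IAA29 0.91) and in acs2C 1 (GH3.3 0.39), with 3, 2, 3 and 0 called adjusted over the list alone. WES1 and IAA29 differed from the other lines by -0.75 and -0.62 in acs2B and -0.64 and -0.99 in acs6E, and GH3.3 by -0.66 in acs2B (adjusted p = 0.0034). In acs9B 4 of the 5 were higher than in the other lines (IAA29 by 1.38, WES1 by 0.56, GH3.3 by 0.49 and GH3.1 by 0.22, adjusted p = 3.6e-05, 0.0028, 0.0066 and 0.023), in acs2C 2 (IAA29 by 0.80 and GH3.3 by 0.38, adjusted p = 0.0052 and 0.032), and in acs5C LBD29 was lower by -0.19 (adjusted p = 0.049). The camera test did not call the list in these lines against Col (adjusted p = 0.64, 0.64, 0.14 and 0.64) or against the other lines (0.17 in acs9B). Leaving out 1 array ended the GH3.3 and IAA29 calls of acs2B against Col (without acs2B replicate 1 or 3 or Col replicate 1 or 3, adjusted p = 0.054 to 0.12, and GH3.3 also without acs2B replicate 2, 0.060), the WES1 call of acs2B (without replicate 1, 0.065), and the GH3.3 calls of acs9B (without replicate 1 or 3 or Col replicate 2 or 3, 0.067 to 0.17) and acs2C (without replicate 1 or 3 or Col replicate 2 or 3, 0.073 to 0.26).

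The ethylene-induced list had 3 measured members: ARL, a gene of organ growth that responds to ethylene and brassinosteroid, PDF1.2 and RTE1. ARL was higher in acs5D by 0.91 (0.80 ± 0.17 against the other lines, adjusted p = 0.021). RTE1 was lower in acs2B (-0.30), acs6E (-0.35) and acs5C (-0.21), and against the other lines it differed by -0.28, -0.28 and -0.11, the last not called (adjusted p = 0.31). RTE1 was higher than in the other lines in acs9B by 0.31 (adjusted p = 0.00081) and in acs2C by 0.24 (adjusted p = 0.0070), and ARL lower in acs6E by -0.61 (adjusted p = 0.018). From Col they differed by 0.09, 0.08 and -0.15 and were not called. PDF1.2 was higher in acs2B by 0.75 (0.42 against the other lines, adjusted p = 0.27). Adjusted over the list alone, 0 members were called in acs1A, 2 in acs2B, 0 in acs2C, 0 in acs4A, 2 in acs5C, 1 in acs5D, 1 in acs6E and 0 in acs9B, and camera gave adjusted p of 0.80 to 0.93. The RTE1 call of acs5C was lost without any 1 of its arrays or Col replicate 1 or 2 (adjusted p = 0.078 to 0.15), and the PDF1.2 call of acs2B without acs2B replicate 1 or 2 or Col replicate 2 or 3 (0.099 to 0.22). EIN3 was higher in acs2C by 0.25 (0.24 against the other lines, adjusted p = 0.035), a call against Col that was lost without any 1 of the 6 arrays (0.056 to 0.11), and it was not called against Col in the other single lines.

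In flavonoid and anthocyanin synthesis 1 of 3 members was lower in acs2C (DFR -0.54), acs5C (AT5MAT -0.32), acs5D (DFR -0.85) and acs9B (AT5MAT -0.45), and 1 was higher in acs2B (UF3GT 0.46). The differences of these genes from the other lines were -0.48, -0.11, -0.73, -0.25 and 0.49, and all but AT5MAT in acs5C (adjusted p = 0.53) were called. DFR was also higher than in the other lines in acs1A by 0.48 (adjusted p = 0.021) and in acs6E by 0.47 (adjusted p = 0.015). Its differences from Col there, 0.22 and 0.05, were not called. Adjusted over the list alone, 1 member was called in acs1A, 1 in acs2B, 2 in acs2C, 0 in acs4A, 1 in acs5C, 2 in acs5D, 0 in acs6E and 1 in acs9B. The list was not called in any line (adjusted p = 0.13 to 0.97). The DFR call of acs2C was lost without Col replicate 2 (adjusted p = 0.070), and the AT5MAT call of acs5C after a second quantile normalization (0.083) and without acs5C replicate 1 or Col replicate 1 or 2 (0.057 to 0.19). Of the root tissue markers EXPA7, EXPA18 and PYK10, limma called 0 against Col in the 8 lines, with 1 at an unadjusted p under 0.05 in acs5C, 2 in acs6E and 0 in the other lines. Adjusted over the list alone 2 were called in acs6E, and camera gave 0.64 to 0.93. Compared with the other lines EXPA18 was higher in acs6E by 0.32 ± 0.09 (adjusted p = 0.020), and no other root marker was called.

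The higher order lines were compared with their own Col arrays, where 0 to 3 of 45 control transcripts differed. AT3G62550 rose in all 4 lines, by 1.31 in penta, 1.45 in hexa, 2.82 in hepta and 2.14 in miR, and AT3G62950 by 2.15, 1.02, 1.92 and 2.01. AT3G15630 rose by 1.17 to 2.05, GAT1_2.1, a gene of the glutamine amidotransferase family, by 0.84 to 1.90, CCL by 0.72 to 1.76 and CHX16, a putative cation and proton exchanger, by 0.70 to 1.49. The 4 reference genes gave 0 calls by limma in all 4 lines, with 0 at an unadjusted p under 0.05 and 0 adjusted over the list alone (camera adjusted p = 0.65 to 0.83). Genes that fell in all 4 lines included CHIL, a chalcone isomerase-like protein of flavonoid synthesis (-0.51 to -1.31), ASPGB1, an asparaginase (-0.72 to -0.90), and MYR2, a MYB-related transcription factor (-0.55 to -1.09). In all 4 lines 184 probe sets rose and 92 fell. All 4 were compared with the same 3 Col arrays, so their agreement is not an independent check. In the single set AT3G62550, AT3G62950, AT3G15630 and CCL went the other way in acs6E (-3.27, -2.43, -2.18 and -2.0 against Col). In penta the CHIL call was lost without any 1 of the 6 arrays (adjusted p = 0.053 to 0.16) and the CHX16 call without penta replicate 2 or 3 or Col replicate 1 (0.066 to 0.11) and on the 6 arrays alone (0.079). The number of calls was 729 in penta, 1830 in hexa, 2739 in hepta and 4748 in miR.

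**Figure D3:**
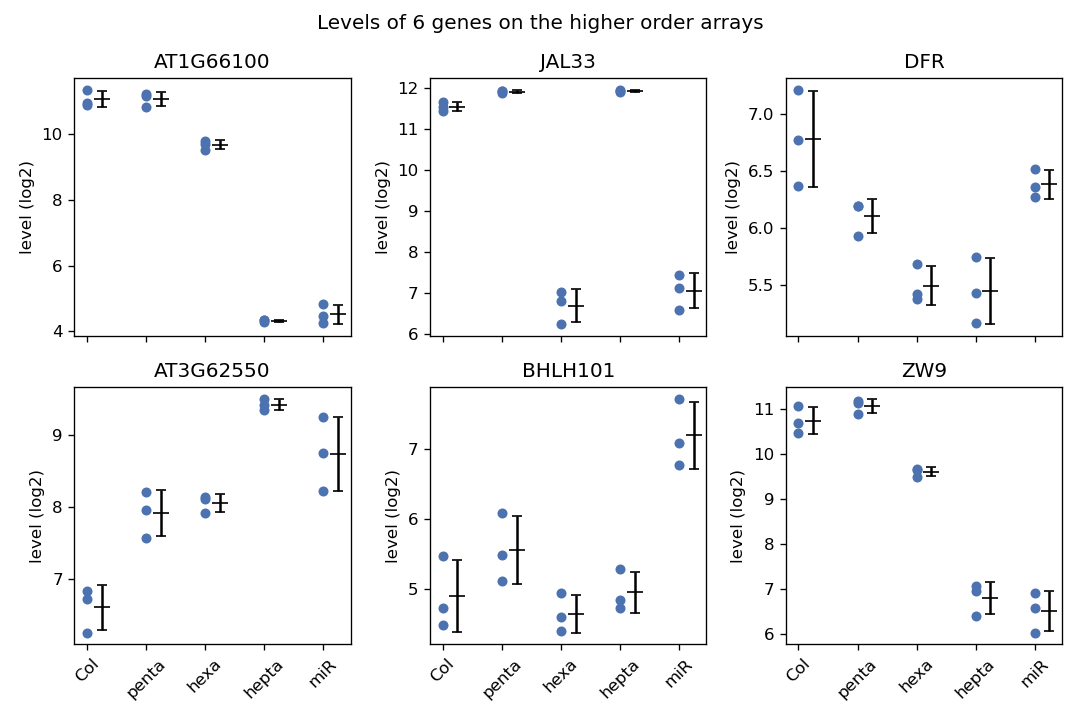
Levels (log2) of 6 genes on the 15 higher order arrays, with 1 point per array and, beside each group, its mean and SD (n = 3). AT1G66100 and ZW9 lay low in hepta and miR, JAL33 in hexa and miR, and BHLH101 was high in miR.

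In penta, 472 probe sets rose and 257 fell. AT3G62950 was at 6.28 ± 0.24 against 4.13 ± 0.21 in Col (2.15 ± 0.16, adjusted p = 1.6e-06), AT3G15630 rose by 1.49 ± 0.16 and CCL by 1.12 ± 0.15. NAMT1 rose by 1.06 ± 0.17 and the ubiquitin ligase gene ATL8 by 0.79 ± 0.10. AT4G36430 fell by 1.32 on the log2 scale (SE 0.18, adjusted p = 0.00048), MYR2 changed by -0.83 ± 0.12, ASPGB1 by -0.76 ± 0.12 and LHCB4.3, of the light-harvesting complex, by -0.62 ± 0.08. DFR was called at -0.68 ± 0.17 (adjusted p = 0.034), but not on the 6 arrays alone (adjusted p = 0.079) or without penta replicates 1, 2 or 3 or Col replicates 1 or 2 (adjusted p = 0.058 to 0.20). The count of 729 fell to 318 without penta replicate 1, 281 without penta replicate 2, 258 without Col replicate 1 and 285 without Col replicate 3.

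In hexa, 1009 probe sets rose and 821 fell. After a second quantile normalization more fell than rose (883 higher and 975 lower). The jacalin-related lectin gene JAL33 was at 6.70 ± 0.40 against 11.54 ± 0.11 in Col (-4.85 ± 0.17, adjusted p = 2.7e-12), AT5G03350 changed by -3.73 ± 0.19, AT5G26260 by -3.47 ± 0.12 and CSA1, a TIR-NB-LRR protein, by -2.51 ± 0.11. SAG29 changed by -2.12 ± 0.26. AT5G15360 rose by 3.28 ± 0.18, from 5.34 ± 0.56 to 8.62 ± 0.10, and AT1G50290 by 3.26 ± 0.09 (adjusted p = 4.5e-14). The cytochrome P450 gene CYP71B22 rose by 1.26 ± 0.10 and ACLA-2, a subunit of ATP citrate lyase, by 1.01 ± 0.08. DFR changed by -1.29 ± 0.17 (adjusted p = 7.2e-05) and CHIL by -1.31 ± 0.12.

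In hepta, 1584 probe sets rose and 1155 fell. That balance turned after a second quantile normalization (1368 higher and 1420 lower). AT1G66100 was at 4.33 ± 0.03 against 11.08 ± 0.24 in Col (-6.74 ± 0.14, adjusted p = 1.5e-15), ZW9, a TRAF-like family gene, at 6.8 ± 0.35 against 10.73 ± 0.30 (-3.94 ± 0.19), and AT4G02540 changed by -2.99 ± 0.13. AT5G26260, which was low in hexa, changed by -3.34 ± 0.12, whereas JAL33 was at 11.91 ± 0.03 against 11.54 ± 0.11 in Col. DFR changed by -1.33 ± 0.17 and TBL26 by -1.18 ± 0.21. AT3G62550 rose from 6.61 ± 0.31 to 9.43 ± 0.08 (2.82 ± 0.20, adjusted p = 4.3e-08), CCL by 1.76 ± 0.15, ACLA-2 by 1.39 ± 0.08 and SUFE2, of iron-sulphur cluster assembly, by 1.2 ± 0.09. The 2739 calls became 1797 without Col replicate 1.

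The miR line, which the labels do not describe further, had 2789 probe sets higher and 1959 lower than Col. A second quantile normalization gave 2341 higher and 2395 lower. AT1G66100 (-6.56 ± 0.14), JAL33 (-4.49 ± 0.17), ZW9 (-4.23 ± 0.19) and CSA1 (-2.90 ± 0.11) fell as they had in hepta or hexa. BHLH101 was at 7.19 ± 0.48 against 4.90 ± 0.51 (2.29 ± 0.27, adjusted p = 9.1e-06), AT2G15560 at 8.38 ± 0.18 against 5.30 ± 0.13 (3.08 ± 0.09, adjusted p = 1.4e-13), and AT5G60250 rose by 2.42 ± 0.12. GAT1_2.1 rose by 1.90 ± 0.13, ACLA-2 by 1.58 ± 0.08, the beta-glucosidase gene BGLU45 by 1.43 ± 0.08 and the defence-related transcription factor gene WRKY53 by 1.37 ± 0.16. OCT1, an organic cation transporter gene, fell by 1.33 on the log2 scale (SE 0.14). The control transcripts differed at 3 of 45 probe sets in this line, and its arrays had the widest spread of the set (median SD 0.106 against 0.0841 to 0.0889 in the other groups).

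Direct comparisons separated the higher order lines. Between hexa and penta 774 probe sets were higher and 889 lower in hexa, with JAL33 (-5.21 ± 0.17), AT5G26260 (-3.96 ± 0.12), CSA1 (-2.54 ± 0.11) and SAG29 (-2.22 ± 0.26) among the lower and AT1G50290 (3.14 ± 0.09) among the higher. Between hepta and hexa 551 were higher and 348 lower in hepta. JAL33 was higher in hepta by 5.22 ± 0.17 and CSA1 by 1.49 ± 0.11, and AT1G66100 (-5.36 ± 0.14), AT4G02540 (-3.21 ± 0.13) and ZW9 (-2.81 ± 0.19) were lower. Between miR and hepta 1207 were higher and 975 lower in miR, with AT4G02540 (3.31 ± 0.13), BHLH101 (2.23 ± 0.27) and the beta-glucosidase gene BGLU28 (1.59 ± 0.15) higher and JAL33 (-4.86 ± 0.17) and SUFE2 (-1.64 ± 0.09) lower. Between miR and hexa 1073 were higher and 709 lower in miR, with BHLH101 (2.53 ± 0.27) and the defensin gene PDF2.1 (1.41 ± 0.15) higher and AT1G66100 (-5.17 ± 0.14) and ZW9 (-3.10 ± 0.19) lower. DFR was lower in hexa than in penta (-0.61) and higher in miR than in hepta (0.93) and hexa (0.89), and the call between hexa and penta was lost without hexa replicate 2 or 3 or penta replicate 1 or 2 (adjusted p = 0.10 to 0.13). Of the 45 control transcripts limma called 0 between hexa and penta (1 at an unadjusted p under 0.05), 0 between hepta and hexa (0), 2 between miR and hepta (8) and 1 between miR and hexa (4). Counts moved by over 1.5 times when 1 array was left out: hexa against penta gave 1013 without hexa replicate 1, 958 without penta replicate 1 and 920 without penta replicate 2, and hepta against hexa gave 583, 585 and 575 without hepta replicate 2, hepta replicate 3 and hexa replicate 1. Counts for miR became 1411 without hepta replicate 1 in the comparison with hepta, and 1151 without miR replicate 2 and 1017 without hexa replicate 1 in the comparison with hexa, while the 6 arrays alone gave 1392 and 1040.

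Of the ethylene-induced genes, ARL rose in all 4 higher order lines, by 0.55 ± 0.12 in penta, 1.01 ± 0.12 in hexa, 0.84 ± 0.12 in hepta and 0.69 ± 0.12 in miR. RTE1 rose in miR by 0.37 ± 0.08, and PDF1.2 was not called against Col in any line. The list thus had 1, 1, 1 and 2 of 3 members higher in penta, hexa, hepta and miR, and 2, 1, 2 and 3 adjusted over the list alone. It passed in miR (camera adjusted p = 0.028, and adjusted p = 0.17 with an estimated correlation), but not without miR replicate 3 (0.068) or Col replicate 1 (0.051), and had adjusted p of 0.053 to 0.081 in the other lines. It also passed in hexa without Col replicate 2, penta replicate 2 or 3, hexa replicate 1 or hepta replicate 1 (0.039 to 0.047) and in penta without penta replicate 2 (0.047). EIN3, a central transcription factor of ethylene signalling, rose in hexa by 0.28 ± 0.08, in hepta by 0.43 ± 0.08 and in miR by 0.28 ± 0.08, and differed by 0.24 in penta (adjusted p = 0.11). The ACC oxidase gene AT1G12010 was not called in any of the 4 lines (differences of -0.14 to 0.25). The ARL call in penta was lost without penta replicate 3 or Col replicate 1 or 3 (adjusted p = 0.057 to 0.086), the EIN3 call in hexa without hexa replicate 2 or 3 or Col replicate 1 or 2 (0.071 to 0.14) and on the 6 arrays alone (0.062), and the EIN3 call in miR without Col replicate 1 (0.079).

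The flavonoid and anthocyanin synthesis list passed toward lower levels in penta (camera adjusted p = 0.015), hexa (0.0020) and hepta (0.0046), and these had adjusted p = 0.18, 0.17 and 0.17 with an estimated correlation. Of 3 measured members, 1 fell in penta (DFR), 2 in hexa and 2 in hepta (DFR, and UF3GT by -0.66 ± 0.12 and -0.67 ± 0.12), and 1 in miR (UF3GT, -0.65 ± 0.12), with 2 in each line adjusted over the list alone. AT5MAT differed by -0.12 to -0.23 and was not called. The call of the list in penta was lost without Col replicate 1 (0.090), the DFR call in penta was lost in 5 of the 6 fits with 1 array left out (0.058 to 0.20), and in miR the list was not called (adjusted p = 0.05 after rounding). It passed there without Col replicate 2 or 3, any 1 of the penta arrays or hepta replicate 1 or 2 (0.013 to 0.049).

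Auxin response genes rose in hepta, where 3 of 5 members were higher over all probe sets and 3 adjusted over the list alone (camera adjusted p = 0.027, and adjusted p = 0.18 with an estimated correlation). In penta 1 was higher and 2 adjusted over the list alone, in hexa 2 and 3, and in miR 2 and 2, without a call of the list (camera adjusted p = 0.081, 0.05 after rounding and 0.077). With 1 array left out the list passed in hexa without Col replicate 2, any 1 of the penta arrays, hexa replicate 2 or hepta replicate 1 or 2 (0.023 to 0.049), in penta without penta replicate 2 or 3 (0.05 after rounding and 0.034) and in miR without Col replicate 2 (0.045). The auxin-conjugating enzyme gene WES1 rose by 0.52 ± 0.08, 0.41 ± 0.08, 0.72 ± 0.08 and 0.64 ± 0.08 in penta, hexa, hepta and miR, GH3.3, of the same family, by 0.72 ± 0.10, 0.35 ± 0.10 and 1.24 ± 0.10 in hexa, hepta and miR, and IAA29 by 0.79 ± 0.15 in hepta. GH3.1 and LBD29 were not called in any of these lines. The GH3.3 call in hepta was lost without hepta replicate 2 or 3 or any 1 of the Col arrays (adjusted p = 0.055 to 0.083).

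The cold and drought list passed in hexa with a median of -0.36 (camera adjusted p = 0.011, and adjusted p = 0.17 with an estimated correlation), although 1 of 4 members was called over all probe sets and 1 adjusted over the list alone. That member is the probe set shared by KIN1 and KIN2 (-1.30 ± 0.10), both on the list. COR15A differed by -0.59, COR15B by -0.12 and COR47 by -0.04 without being called. In penta limma called 0 members (0 at an unadjusted p under 0.05 and 0 adjusted over the list alone), in hepta 1 higher and 1 lower, and in miR 1 lower, with 2 and 1 adjusted over the list alone and camera adjusted p of 0.79, 0.86 and 0.05 after rounding, none called. The list passed in miR without Col replicate 3, any 1 of the penta arrays, hepta replicate 1 or miR replicate 2 (0.018 to 0.047). Of the root tissue markers limma called 0 in all 4 lines, with 1, 0, 2 and 0 at an unadjusted p under 0.05 in penta, hexa, hepta and miR. Adjusted over the list alone 1 was called in penta, and camera gave adjusted p of 0.097 to 0.98.

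Overlaps between lines were set against values for comparisons that share control arrays. In the single set the log2 differences of 2 lines correlated across probe sets at r = 0.28 to 0.87 (28 pairs, median 0.67), where unchanged groups simulated against shared Col arrays gave 0.50, and the covariance lay above the simulated 0.0053 in all 28 pairs. The lines acs2B and acs6E correlated at 0.86 and acs2C and acs9B at 0.87, while acs2B and acs2C, named for the same gene, correlated at 0.41 and acs5C and acs5D at 0.74. In acs2B and acs2C 1126 probe sets were higher and 1371 lower in both, against 279 and 414 for independent lists, and in acs5C and acs5D 1111 and 1356 against 145 and 246. In the higher order set r was 0.37 to 0.72 (6 pairs, simulated 0.50), the covariance was above the simulated 0.00521 in all 6 pairs, and hepta and miR shared 1055 higher and 721 lower probe sets against 194 and 99.5. The simulation gave every group the same spread, but the single-set Col arrays spread most (median SD 0.120 against 0.0722 to 0.101 in the lines). A wider spread of shared Col arrays raises r and covariance of unchanged lines, so the simulated single-set values lie too low. Values above them do not by themselves show shared changes. The 3 Col arrays of a set cannot be split into parts of 2, so part of the excess may come from the shared controls. Between the sets, where no control array is shared, r ranged from -0.44 (acs6E and penta) to 0.25 (acs9B and hexa) with a median of -0.005. Probe sets are not independent replicates. By the F-test, 11367 probe sets differed among the single groups, with 5779 and 5238 without replicate 2 or 3 of every group, and 5580 among the higher order groups, with 2843 and 2350 without replicate 1 or 2 of every group.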

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

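The comparison of control transcripts, the correlation with deviations of arrays from their group means and the fit of acs2B and acs2C with the bioC level as a batch term were chosen only after the results were seen, while the same-sign share, the RNA integrity test and the root marker test were chosen before.

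All 8 single lines differed from the single-set Col arrays in a shared direction at 1030 probe sets, and a signal outside the plant transcripts moved with them, since 40, 29, 41, 39, 37, 38, 35 and 35 of 45 control transcripts differed from Col in acs1A, acs2B, acs2C, acs4A, acs5C, acs5D, acs6E and acs9B. Of the 1030 probe sets, 47.2% had the same sign in the mean of the higher order lines against their own Col, against 49.6% of all probe sets. The 95% interval was 44.1 to 50.3 (exact binomial, for counting error only, with probe sets that are not independent). By line the share was 54.6% in penta, 54.1% in hexa, 52.04% in hepta and 36.7% in miR. These values argue against an effect of losing ACS genes, shared by the higher order lines, as the main source of the 1030 calls. A smaller shared effect is not excluded. The probe sets were chosen by their distance from the single-set Col arrays, and a shift of those arrays would hide it. The share of 47.2% goes with the hypothesis that the Col arrays of the single set stand apart for a reason other than genotype. It leans on miR, which the labels do not describe further and which alone had fewer same than opposite signs. In penta, hexa and hepta same signs were a slight majority, so these lines by themselves do not decide for that hypothesis. In the control transcripts these Col arrays did stand apart, since at least 64.4% differed in every line. Between acs5C and acs5D 22.2% differed, but all 10 of those were hybridization controls. Of 27 labelling controls limma called 0 between acs5C and acs5D and 0 between acs2B and acs2C, against 15 to 24 between a line and Col. How many plant calls come from labelling or hybridization stays open and cannot be told apart from genotype. RNA integrity stays open too, because the 3 prime minus 5 prime difference of control genes was 1.32 ± 0.04 (SD, n = 3) on Col, only 0.08 above the highest line mean. An effect of ACS loss special to the single lines was not tested and stays open as well.

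The lines acs2B and acs2C, named for one gene, differed at 4859 probe sets in the direct test, and at 4644 with the bioC level as a batch term. A different share of root tissue is argued against by the root markers, all 3 of which shifted little between these lines (EXPA7 by 0.10, EXPA18 by 0.11 and PYK10 by 0.03), with a median of 0.10. An expression axis that also varies between arrays of 1 genotype stays open: the first component of the deviations of 18 arrays of other groups from their group means correlated with acs2B minus acs2C across probe sets at 0.42 in size, and over 15 of them, without Col, at 0.32, which decides neither way. In the higher order set the first such component, with 20.1% of the deviations, gave 0.03, so the axis did not lead the deviations there. Later components were not examined. The acs4A arrays, with which the value was 0.78, were left out because their replicate 1 was singled out on the component that also parts acs2B from acs2C. The 0.78 is therefore no independent test. The acs4A scores on that component, -26.8, 5.9 and 13.8, spanned a range like that between acs2C (-18.1 to -18.4) and acs2B (16.8 to 22.3). Arrays of 1 genotype thus did differ along it, although through 1 array. A difference between the genotypes of acs2B and acs2C stays open, since no named probe set measured the mutated gene.

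Between acs5C and acs5D, 521 probe sets differed in the direct test. Between hexa and penta the test gave 1663, between hepta and hexa 899, between miR and hepta 2182 and between miR and hexa 1782. In miR, 3 of 45 control transcripts differed from Col, with 15 at an unadjusted p under 0.05, a signal outside the plant transcripts.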

How the results depend on the processing

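Comparisons with the other lines of the same bioC level, the batch term for that level, and the fits without acs4A replicate 1 and without the miR arrays were chosen only after the results were seen, and the other alternatives beforehand. A filter on low values, an intensity trend with a robust prior and a second quantile normalization kept every count within 1.5 times, as did the fits without acs4A replicate 1 or miR where they applied. Quantile normalization moved the share of higher calls by 0.909 to 9.31 percentage points. This turned the majority from higher to lower in hexa, hepta and miR and from lower to higher in acs2B, acs2C, acs4A, acs5C, acs5D and acs6E, so the balance of higher and lower calls in these lines depends on the scaling. The 6 arrays alone, with fewer samples behind the spread, gave 2319 calls in acs1A, 2543 in acs2B, 3600 in acs2C, 571 in acs4A, 1827 in acs5C and 1836 in acs5D. They gave 4252 in acs6E, 2843 in acs9B, 1068 between acs5C and acs5D, 1392 between miR and hepta and 1040 between miR and hexa. The other counts stayed within 1.5 times. These fits also use only the spread of the 2 groups compared. The median SD was 0.120 on the single-set Col arrays, 0.0732 in acs5C and 0.0726 in acs5D, so the estimate shared by all groups fits them unequally. Against the other lines of the same bioC level, acs1A had 1090 calls, acs2B 3209, acs2C 3091, acs4A 951, acs5C 859, acs5D 329 and acs6E 3751, and camera called 0 of the lists fixed beforehand and 12 of the tests of added families; the cause was not tested. For the lists fixed beforehand, camera with an estimated correlation gave 0 calls in both sets, against 1 in the single and 6 in the higher order set, while fry gave 10 and 14. For the added families camera gave 4 calls in the single and 4 in the higher order set, 0 and 0 with an estimated correlation, and fry 27 and 7. The replicate numbers did not pair the arrays: same-numbered arrays correlated above 0.1 throughout in 0 of 36 single and 0 of 10 higher order pairs of groups, and the median r was 0.00777 for the same number and -0.00363 for other numbers. With the replicate block the list tests of the single set gave 5 calls, the cold and drought list also passing in acs1A, acs2C, acs5C and acs6E, the higher order set gave 6, and the counts stayed within 1.5 times (4858 in acs1A, 760 in penta). Leaving out 1 array gave 3322 to 4833 calls in acs1A, 3750 to 5060 in acs2B, 4722 to 6344 in acs2C, 3828 to 4555 in acs4A, 3079 to 4164 in acs5C, 2806 to 4009 in acs5D, 5090 to 6208 in acs6E, 4224 to 5947 in acs9B, 3513 to 4079 between acs2B and acs2C and 239 to 372 between acs5C and acs5D. In the higher order set the ranges were 258 to 889 in penta, 1264 to 1423 in hexa, 1797 to 2394 in hepta, 3648 to 4244 in miR, 920 to 1553 between hexa and penta, 575 to 660 between hepta and hexa, 1411 to 1976 between miR and hepta and 1017 to 1875 between miR and hexa. Without 1 replicate number the F-tests gave 5238 to 9379 calls in the single and 2350 to 4055 in the higher order set, and without 1 array the list tests gave 1 to 5 and 4 to 12. Arrays whose omission moved the list tests by over 1.5 times were Col 2 (4 calls), acs1A 2 (2), acs2C 2, acs9B 1 and acs9B 3 (5 each) in the single set, and Col 2 (10), penta 2 (12), penta 3 (11) and hepta 1 (10) in the higher order set. Of the values of single genes and list members past the threshold, each tested under the settings that applied to it, none turned its direction. Under the filter 419 kept their side of the threshold (0 lost), but values on the dim probe sets that it removed were not tested there. The number kept was 596 after quantile normalization (6 lost), 586 with the trend (16 lost) and 531 on the 6 arrays (71 lost). It was 312 without acs4A replicate 1 (0 lost) and 169 without miR (1 lost). Of the fits with 1 array left out 3321 kept and 291 lost the call. The replicate block left 596 past the threshold and 6 not. Probe sets near background carry values that RMA compresses, which limits calls of dim genes; with the filter, which tests fewer probe sets, the count was 4045 against 4860 in acs1A and 3771 against 4748 in miR. The planned levels of ACS genes were not run, since no ACS gene had a named probe set.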

Other observations

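The comparison of families with the other lines of the same bioC level, the search for blocks, the starvation list and the counts of splits were chosen only after results were seen; the test near the ACS genes was chosen before.

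Small heat shock proteins, chaperones that bind unfolded proteins, were measured through 7 genes and split the single lines. Against Col 5 were lower in acs2C (median -0.48), 4 in acs4A (-0.42) and 5 in acs9B (-0.50), with camera adjusted p of 0.014, 0.017 and 0.0073, and adjusted p = 0.55 with an estimated correlation in each, in lines where 41, 39 and 35 of 45 control transcripts also differed. Against the other lines of the same bioC level, 5 were higher in acs2B (median 0.54, camera adjusted p = 0.0012) and 6 in acs6E (0.51, adjusted p = 0.00024), while 5 were lower in acs2C (-0.50, adjusted p = 6e-04), 6 in acs9B (-0.56, adjusted p = 6e-04), 2 in acs4A (-0.27, adjusted p = 5e-04) and 2 in acs5D (-0.08, adjusted p = 0.0016), and these had adjusted p = 0.27 to 0.35 with an estimated correlation. Between acs2B and acs2C, AT5G51440 was higher in acs2B by 1.48 ± 0.23 (SE, limma adjusted p = 1e-04), AT1G54050 by 1.03 ± 0.17, AT2G29500 by 0.82 ± 0.13 and AT1G53540 by 0.80 ± 0.08 (adjusted p = 2.8e-06). In hepta AT1G54050 fell by 2.11 on the log2 scale (SE 0.20, adjusted p = 1.4e-06), but the family was not called in the higher order lines. The calls against Col were lost in acs2C and acs4A without Col replicate 3 (adjusted p = 0.054 and 0.062) and in acs4A without acs4A replicate 1 (0.15), and the family passed in acs5D without Col replicate 1 (0.044). The genes named here and in the next 2 paragraphs were chosen after their values were seen.

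Of 69 plastid-encoded genes, 12 fell and 1 rose in hepta (median -0.13) and 23 fell and 1 rose in miR (-0.20), with camera adjusted p of 1.3e-06 and 1.5e-09, and adjusted p = 0.57 with an estimated correlation in both. Of the 45 control transcripts limma called 3 in miR, all labelling controls, and 0 in hepta, with 15 and 0 at an unadjusted p under 0.05. The ribosomal protein gene rpl14 changed by -0.58 ± 0.11 in hepta and -0.69 ± 0.11 in miR, the NDH complex gene ndhG by -0.58 ± 0.12 and -0.57 ± 0.12, and the photosystem II gene psbD by -0.65 ± 0.14 in miR. In hexa the list was not called (adjusted p = 0.17), except without Col replicate 3 (0.012) or hexa replicate 2 (0.00014). In acs5D 16 of these genes were higher and 4 lower than Col (median 0.09, camera adjusted p = 0.0073, and adjusted p = 0.98 with an estimated correlation), where 38 of 45 control transcripts also differed, and the call was lost without Col replicate 1 (0.07). Against other lines of the same bioC level camera called the list higher in acs5D (0 members called, median 0.06, adjusted p = 0.0021) and acs1A (4 higher, median 0.07, adjusted p = 5e-04) and lower in acs5C (2 higher and 3 lower, median -0.08, adjusted p = 0.042), with adjusted p = 0.83, 0.79 and 0.99 with an estimated correlation, and did not call it in acs9B (9 higher and 1 lower, adjusted p = 0.53). In acs9B, with 35 such control transcripts, 18 were higher and 3 lower (adjusted p = 0.066), and the list passed after a second quantile normalization (0.047) and without Col replicate 2, acs5C replicate 1, acs9B replicate 1 or acs9B replicate 3 (0.0030 to 0.039).

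UDP-glycosyltransferases, enzymes that attach sugars to small molecules such as flavonoids, changed in both directions in hexa, where 9 of 47 fell and 3 rose, and in miR, where 14 fell and 7 rose. UGT78D2 and UGT78D1, which glycosylate flavonols, changed by -0.64 ± 0.10 and -0.55 ± 0.10 in miR, UGT72E2, of lignin precursor metabolism, by -0.79 ± 0.08 and UGT85A2 by 0.79 ± 0.09 (limma adjusted p = 5.6e-06). The family was called in both lines only at the edge of the threshold (adjusted p = 0.05 after rounding, and adjusted p = 0.57 with an estimated correlation). Both calls were lost after a second quantile normalization (0.059) and without any 1 of Col replicates 2 and 3, the 3 penta arrays, hexa replicate 3, hepta replicate 1 and miR replicates 1 and 3 (0.051 to 0.20). In the comparison with other lines of the same bioC level, 3 of 7 tubulin genes were lower in acs1A (median -0.14) and 3 higher in acs4A (0.19), with camera adjusted p of 0.00069 and 0.00081 and adjusted p = 0.091 with an estimated correlation in both. Class III peroxidases were called lower in acs5D in that comparison (3 of 53 lower, median -0.10, camera adjusted p = 0.0021, and adjusted p = 0.50 with an estimated correlation). In acs6E 8 were higher and 1 lower without a call (adjusted p = 0.09). Against Col that family passed toward higher levels in acs6E only without Col replicate 1 (0.0076 against 0.079). Of 14 glutathione S-transferases 7 were lower than Col in acs2C (median -0.21), where 41 of 45 control transcripts also differed. Of the settings run, camera called that family there only without Col replicate 1 or acs2C replicate 2 (0.044 and 0.037 against 0.071), and 1 member was lower than in the other lines.

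The lines acs2B and acs6E shared 1861 higher and 2201 lower probe sets against Col, where independent lists would share 310 and 440, and 8 were called in opposite directions. The lines acs2C and acs9B shared 1712 and 2336, against 300 and 485 for independent lists, with 3 opposite. The log2 differences of these pairs correlated at 0.86 and 0.87 across probe sets, where unchanged groups simulated against shared Col arrays gave 0.50, and their covariances were 0.0608 and 0.0595 against 0.0053. These simulated values lie too low, because the simulation gave every group the same spread while the Col arrays of this set spread most. Part of the overlap may come from the shared Col arrays, whose distance from all lines is the subject of the same-sign share of 47.2%. Against the higher order set, with no shared control, acs6E and penta had 465 probe sets called in opposite directions and 14 higher and 9 lower in both. The lines acs9B and hexa had 158 in opposite directions and 253 higher and 326 lower in both (110 and 120.4 for independent lists), and acs2C and hexa 173, 275 and 302 (122 and 119). Across the 4 higher order lines the log2 differences correlated at -0.44 to -0.19 with those of acs6E and acs2B, and at 0.08 to 0.25 with those of acs9B and acs2C.

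A further pattern is the position of strongly changed genes, those called with at least a 2-fold change. For the single lines each probe set was counted once per line and the counts were summed over the 8 lines. Within 200 genes of the line's own ACS gene, 8 of 1082 such entries were strongly changed, against 424 of 94856 away from ACS genes (odds ratio 1.66, 95% interval 0.71 to 3.31, Fisher's exact p = 0.16), and near the other ACS genes 60 of 11550 were (odds ratio 1.16, 0.87 to 1.53, p = 0.27). The lines share Col arrays and probe sets recur, so the entries are not independent and the intervals and p-values are too narrow. Neither a local effect nor a neighbourhood effect common to all lines was shown or excluded. In the higher order lines, pairs of such genes 10 to 200 genes apart numbered 57 in hexa, 85 in hepta and 161 in miR, against means of 29.1, 57.5 and 109 in 1000 random draws, of which 0, 2 and 0 gave as many, and 2 in penta against 0.963 (232 of 1000). The ratios were 1.48 in hepta and miR and 1.96 in hexa, and 1 of the 4 lines, penta, exceeded a ratio of 2 (2.08), while single lines reached 1.46 in acs4A (66 of 1000 draws as many), 1.43 in acs2B (40) and 1.29 in acs2C (75), with 0 to 1.16 in the other 5. Sequence differences linked to the crossed-in loci may contribute, as a hypothesis, but single lines came close to hepta and miR, draws reached the real number in hepta, and neither adjacent gene copies nor an effect of lower ACC synthase activity alone was excluded.

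The hypothesis that starvation-induced genes were higher in the higher order lines was tested on 7 named genes not looked at before: the number of lines with a median above 0.3 was 0, with medians of 0.19 in penta, 0.11 in hexa, 0.24 in hepta and 0.19 in miR, and 2, 1, 3 and 2 of the 7 genes were called higher, which decides neither way. Between acs2B and acs2C the median of these genes was -0.49, and 5 of 7 were lower in acs2B.

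Other splits of the same arrays into groups of the same size were counted for each comparison. For the 18 comparisons of 3 with 3 arrays, 1 of the 10 splits, the real one, gave as many calls, and 10 splits are too few for a share under 0.05. The real count and the highest other were 4860 and 3 in acs1A, 5161 and 2 in acs2B, 6053 and 4 in acs2C, 4610 and 1194 in acs4A, 4357 and 6 in acs5C, 4012 and 0 in acs5D, 6559 and 0 in acs6E, and 5820 and 35 in acs9B. They were 4859 and 0 between acs2B and acs2C, 521 and 0 between acs5C and acs5D, 729 and 3 in penta, 1830 and 0 in hexa, 2739 and 0 in hepta and 4748 and 0 in miR. Between hexa and penta they were 1663 and 0, between hepta and hexa 899 and 0, between miR and hepta 2182 and 0 and between miR and hexa 1782 and 0. For the F-tests, of 100 splits including the real one and drawn at random otherwise, 1 gave as many calls, with 11367 against 289 at most in the single set and 5580 against 494 in the higher order set. That share under 0.05 argues against chance as the source of these counts. It does not tell genotype from labelling or hybridization. In the single set the control transcripts part Col from the lines, and the bioC levels largely follow the line names.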
